A study of Danio rerio with 9 samples.

How the data were processed

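Total RNA of zebrafish caudal fin was sequenced in 9 libraries. Per the labels, 3 libraries came from intact fins, 3 from regenerating fins at 3 days after amputation (3 dpa) and 3 from regenerating fins at 7 days after amputation (7 dpa). The libraries were made by RNA fragmentation, random priming and a dUTP second strand, per the labels, and were read on an Illumina HiSeq instrument, per the series design. Whether a library held 1 fish or a pool was not given in the sources used here, so p-values measure only the spread between these samples, which may be technical.

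Per the submitters' processing notes, the tools were cutadapt, TopHat2 2.0.3.12, RSEM and edgeR, with no role given for each. The same notes name hg38, a human genome build, although the organism and the annotated transcript IDs are those of zebrafish. The zebrafish build and the circRNA caller were not given in the sources used here. No coordinates were used. The mRNA and lncRNA tables, as deposited, hold a signal per transcript and library with 2 decimals. Those values are not whole counts, and whether they are FPKM or TPM is not stated per the file headers or labels. Their sequencing depth is therefore unknown, and so is whether both tables were scaled together. The circRNA table holds RPM values deposited per circRNA, and each library sums to the same total. All circRNA values (100%) were whole multiples of the smallest value of their library within a tolerance of 0.001 reads, so reads were recovered. There were 12070 to 16262 circRNA reads per library. Transcripts with an ENSDART ID are called annotated here, and those with a TCONS ID assembled. The mRNA table held 44893 annotated and 10500 assembled transcripts, 3966 and 528 made up the lncRNA table, and 5578 numbered circRNAs the circRNA table.

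None of the transcript or circRNA IDs appeared in the name tables used, which pair gene IDs, not transcript IDs, with symbols (0 of 55393, 0 of 4494 and 0 of 5578). The files do not pair the IDs with gene names. The 31 gene lists with 1134 genes that were fixed before the data were examined therefore matched 0 transcripts and were not tested, and sums per gene and a comparison of circRNAs with host genes were not made. Transcripts of the same gene were tested one by one and can share reads, so their values are not independent.

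Each table was tested with limma 3.58.1 in R 4.3.3 (empirical Bayes with trend and robust settings) on log2(value + pseudocount), with all 9 libraries in one model, 3 contrasts between groups and no covariate. The pseudocount was 1 for mRNA, 0.1 for lncRNA and 1 for circRNA. Transcripts were kept at a value of at least 1 (mRNA), at least 0.1 (lncRNA) or above 0 (circRNA) in at least 3 libraries. Tests were two-sided, and a transcript was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 changes are on the log2(value + pseudocount) scale, which understates the change of low mRNAs and lncRNAs. For circRNAs a pseudocount of 1 RPM lies far below 1 read (61.5 to 82.9 RPM), so zeros inflate the change. For novel_circ_004062 the fitted log2 change at 3 dpa was 6.06, against 4.00 from reads summed over each group. For circRNAs, edgeR 4.0.16 and DESeq2 1.42.0 were also run on the recovered reads. Per-library measures were compared over the 3 groups with an exact permutation test of any difference among them, in Python 3.11.15. It had 280 distinct splits and a smallest possible p of 0.00357, with adjustment over the 9 measures. It is no test of 3 dpa against intact fin alone, where 3 against 3 libraries cannot give an exact permutation p under 0.1.

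The comparisons, their tests, most alternatives and the rule for named transcripts were fixed before the data were examined. The rule took, at 3 dpa against intact fin, the largest changes among called transcripts with every library of one group above every library of the other, and a higher-group mean of at least 10 (mRNA) or 1 (lncRNA and circRNA). Its requirement of a gene symbol could not be met and was dropped, and 2 rises and 2 falls per table are named. The split by annotated and assembled transcripts, the comparison of 3 dpa with 7 dpa calls across the lncRNA and circRNA tables, the expression-level sets and all 9 per-library measures were added after the data were seen. So were the alternatives with an equal mRNA plus lncRNA total, with TMM factors of the mRNA table, with a pseudocount of 1 read for circRNAs and with edgeR and DESeq2 on circRNA reads, a simulation of changes that persist from 3 to 7 dpa, shared calls at an unadjusted threshold, shares of falls by class and level under other scalings, and the assembled share of the lncRNA total with and without its 7 most abundant members.

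The scripts were tested on simulated values for 3 dpa against intact fin with 200 changed transcripts. Among 25001 mRNAs, 14.9%, 64.2% and 97.0% of those changed by 0.5, 1 and 2 on the log2 scale were recovered, with 10 false calls in 127. The data gave far more mRNA calls than the 200 simulated changes, which eases the adjusted threshold. The mRNA shares may therefore understate recovery in the data. Among 1671 lncRNAs the shares were 0%, 22.4% and 63.6%, with 1 false call in 58. A first simulation for circRNAs recovered almost none at a log2 change of 2, so a larger change and a group of well-covered circRNAs were added to the simulation. In that version, over 3213 circRNAs, limma recovered 52% and 84% of well-covered circRNAs (mean of at least 10 reads) at log2 changes of 2 and 4. It recovered 0% and 16% of less covered ones. On the same simulated data edgeR recovered 44% and 96% of well-covered and 0% and 64% of less covered circRNAs. For edgeR a call in either direction counted as recovered, but for limma only a call in the simulated direction. A circRNA without a call may therefore have changed.

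No 2 libraries held identical columns, and circRNA reads of every pair within a group differed by more than sampling noise (chi-square 2.70 to 4.58 times its degrees of freedom), so no pair looked like 1 library deposited 2 times, and each library counted as 1 replicate. Repeat libraries of 1 fish would also exceed sampling noise, so this does not show separate animals. Counting limits cover counting error only.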

Results

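RNA of caudal fins was profiled in intact fins and in regenerates at 3 and 7 days after amputation, with 3 libraries per group. The tables covered mRNA transcripts, long non-coding RNAs (lncRNAs) and circular RNAs (circRNAs), which are joined back to front by splicing. After filtering, 25001 of 55393 mRNA transcripts, 1671 of 4494 lncRNAs and 3213 of 5578 circRNAs were tested. Depth was unknown for mRNA and lncRNA. The circRNA table held 14631 to 16262 reads per intact fin library, 12070 to 13443 at 3 dpa and 12427 to 13507 at 7 dpa. The files do not pair transcript IDs with gene names, so transcripts are described by ID, class and level.

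In the mRNA table the first principal component held 56.0% of the variance and placed the 7 dpa libraries between the other groups. Intact fin libraries lay at -72.7 to -63.5, 7 dpa libraries at 0.0362 to 8.70 and 3 dpa libraries at 58.1 to 66.6. The first component held 30.9% of the variance for lncRNAs and 18.5% for circRNAs, with the 7 dpa libraries again in the middle.

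**Figure D1:**
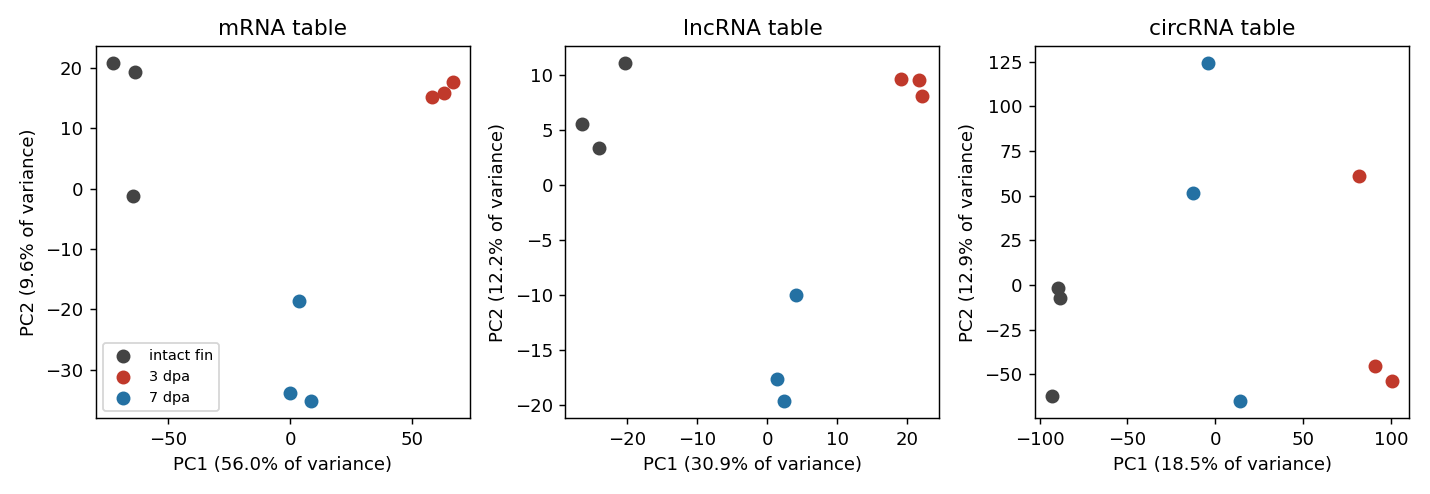
First 2 principal components of each table, 1 point per library, coloured by group, with the percent of variance on each axis. In all 3 panels the 7 dpa libraries lie between intact fin and 3 dpa libraries on the first component, which holds 56.0%, 30.9% and 18.5% of the variance.

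The comparison of 3 dpa regenerates with intact fins asked which transcripts differ early in regrowth. Of the mRNA transcripts, 5510 were higher and 6989 lower, together 12499 of the 25001 tested. A change of at least 2-fold was seen in 2063 of the higher and 2279 of the lower transcripts. Among the 50 most abundant transcripts, 7 rose and 31 fell. The most abundant transcript in all 9 libraries was an annotated one that fell from a signal of 16036 ± 350 (SD, n = 3) to 8781 ± 595, and its share of the mRNA total went from 3.70% ± 0.15 to 2.12% ± 0.14. The balance of directions depended on scaling. With TMM factors 6223 transcripts were higher and 6041 lower, so no majority direction is given. A stricter filter left 8169 calls among 12567 tested.

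ENSDART00000132089 had the largest rise under the naming rule, from 9.07 ± 4.73 in intact fin to 1211 ± 151 at 3 dpa (SD, n = 3; log2 change 7.04, SE 0.33, limma adjusted p = 1.16e-06), and stood at 256 ± 3.2 at 7 dpa. The assembled TCONS_00033479 rose from 6.31 ± 1.85 to 632 ± 72.5 and stood at 218 ± 30.7 at 7 dpa (log2 change at 3 dpa 6.46, SE 0.18, limma adjusted p = 2.05e-07). TCONS_00034811 fell from 229 ± 10.3 to 7.72 ± 4.14 and stood at 110 ± 16.2 at 7 dpa (log2 change at 3 dpa -4.83, SE 0.29, limma adjusted p = 3.31e-06). TCONS_00050791 had signals of 41.6, 16.6 and 38.3 in intact fins, was listed at 0 in all 3 libraries at 3 dpa and had 19.4, 1.02 and 5.33 at 7 dpa (limma adjusted p = 0.000406 at 3 dpa). Its call at 7 dpa was lost in several settings.

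Assembled mRNA transcripts were lower more often than annotated ones at 3 dpa. Of all tested mRNA transcripts, 32.1% of assembled and 26.9% of annotated ones were called lower, and 15.2% and 23.8% higher. At 3 dpa 1651 assembled transcripts fell and 780 rose, so 67.9% of the calls were lower, against 53.0% of annotated calls (5338 lower, 4730 higher). The odds ratio was 1.88 (95% interval 1.71 to 2.06, Fisher's exact test, adjusted p = 1.49e-40), but transcripts are not independent and this p is too small. At 7 dpa against intact fin 61.3% of assembled and 49.3% of annotated calls were lower. Of the tested transcripts, 14.2% of assembled and 12.9% of annotated ones were then called lower, and 8.96% and 13.3% higher. From 3 to 7 dpa the direction of the difference turned, with 27.3% of assembled and 52.4% of annotated calls lower. The shares at 3 dpa were 62.0% and 46.3% with TMM factors and 62.5% and 49.1% with quantile normalization. Among tested lncRNAs, 92 of 480 assembled (19.2%) and 162 of 1191 annotated ones (13.6%) were called lower at 3 dpa, with median log2 changes of -0.55 and -0.40, a difference that was not tested. As a share of calls, most of which were falls in both classes, the lncRNA split did not pass the test, with 83.6% of assembled and 79.0% of annotated calls lower at 3 dpa (odds ratio 1.36, 95% interval 0.716 to 2.65, Fisher's exact test, p = 0.371, adjusted p = 0.557). It was 63.3% and 63.2% at 7 dpa and 10.5% in both classes between the times (Fisher's exact p = 1 in both). The share of the mRNA total held by assembled transcripts was 9.83% ± 0.43 in intact fin, 8.76% ± 0.14 at 3 dpa and 9.27% ± 0.34 at 7 dpa (SD, n = 3; exact permutation p = 0.0179, adjusted p = 0.023 over 9 measures). Assembled lncRNAs held 36.5% ± 1.7 of the lncRNA total in intact fin, 26.4% ± 2.1 at 3 dpa and 31.8% ± 3.3 at 7 dpa (exact permutation p = 0.00714, outside the adjustment over 9 measures). Without the 7 most abundant lncRNAs the shares were 26.3% ± 0.56, 25.3% ± 0.69 and 27.2% ± 1.1 and did not pass the test (exact permutation p = 0.111). The call for the assembled share of the mRNA total was lost when any of 6 libraries was left out, with exact permutation p up to 0.104 without replicate 1 of 3 dpa.

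Among lncRNAs 61 were higher and 254 lower at 3 dpa, with a median log2 change over all tested of -0.45. TCONS_00014589 had signals of 0.01, 0.07 and 0.01 in intact fins and 3.38, 2.27 and 4.13 at 3 dpa (limma adjusted p = 3.37e-05). ENSDART00000155205 was listed at 0 in all intact fins and had 4.46, 0.36 and 4.13 at 3 dpa (limma adjusted p = 0.00577). TCONS_00018578 had 2.18, 1.61 and 2.16 in intact fins and was listed at 0 at 3 dpa (limma adjusted p = 0.00379). ENSDART00000177369 had 1.49, 1.93 and 3.13 in intact fins and 0.23, 0 and 0 at 3 dpa (limma adjusted p = 0.00139). Scaling each library by the lncRNA table itself removed the majority of falls. With TMM factors 104 were higher and 106 lower, and with quantile normalization 112 and 104.

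The lncRNA total per 1000 units of mRNA total was 41.9 ± 4.68 in intact fin, 26.7 ± 2.84 at 3 dpa and 34.4 ± 4.33 at 7 dpa (SD, n = 3; exact permutation p = 0.0107, adjusted p = 0.0161). Without the 7 most abundant lncRNAs, which held 75.7% ± 2.2 of the lncRNA total in intact fin, it was 10.1 ± 0.32, 7.05 ± 0.27 and 8.72 ± 0.71 (exact permutation p = 0.00357, the smallest possible). This measure sets 2 tables against each other that may have been scaled separately. Transcripts at a signal of at least 1 numbered 23194 ± 94 in intact fin, 22158 ± 155 at 3 dpa and 22735 ± 156 at 7 dpa (exact permutation p = 0.00357). That number depends on library scaling. The mRNA total itself was 433478 ± 8440 in intact fin, 413457 ± 4527 at 3 dpa and 420474 ± 12120 at 7 dpa (exact permutation p = 0.107). The 10 most abundant transcripts held 13.6% ± 0.44, 10.22% ± 0.15 and 12.3% ± 0.60 of the mRNA total (exact permutation p = 0.00357).

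Of the circRNAs, 44 were higher and 36 lower at 3 dpa with limma, and 455 had an unadjusted p under 0.05, a number that includes chance. Higher and lower refer to shares of the circRNA reads of a library, so a change in the circRNA total would not show. All libraries of one group lay above those of the other for 19.1% of circRNAs, against 10% expected by chance without ties. Counts moved with the tool. edgeR on recovered reads called 99, and DESeq2 called 43 of the 971 circRNAs to which it gave an adjusted p. With limma, 25 were called with only the 2 groups compared, 35 without the robust setting and 123 with a pseudocount of 1 read (51 higher, 72 lower). The balance also turned without replicate 1 (37 and 40), 2 (38 and 54) or 3 (36 and 58) of 3 dpa. Among the 185 circRNAs with a mean of at least 10 reads per library 30 rose and 23 fell, and among the 3028 others 14 rose and 13 fell. Summed over each group, novel_circ_004062 had 5 reads in intact fin, 65 at 3 dpa and 41 at 7 dpa, and novel_circ_003979 had 3, 39 and 24. novel_circ_004981 had 38, 2 and 15 reads. novel_circ_001757 had 28 reads in intact fin, 0 at 3 dpa and 11 at 7 dpa. With 3 counts over the group in place of the 0, it was 7.57-fold lower at 3 dpa. That value takes the 28 reads as exact and is no firm lower bound. The limma calls of these 4 circRNAs were each lost in several settings.

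At 12070 reads per library, 2429 ± 97 distinct circRNAs were found in intact fin, 2082 ± 15 at 3 dpa and 2330 ± 53 at 7 dpa (SD, n = 3; exact permutation p = 0.00714, adjusted p = 0.0129). With all reads the numbers were 2623 ± 136, 2113 ± 30 and 2378 ± 43. The share of reads in the 10 most abundant circRNAs was 16.5% ± 2.0, 18.4% ± 0.17 and 16.4% ± 0.60, a difference that did not pass the test (exact permutation p = 0.171).

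**Figure D2:**
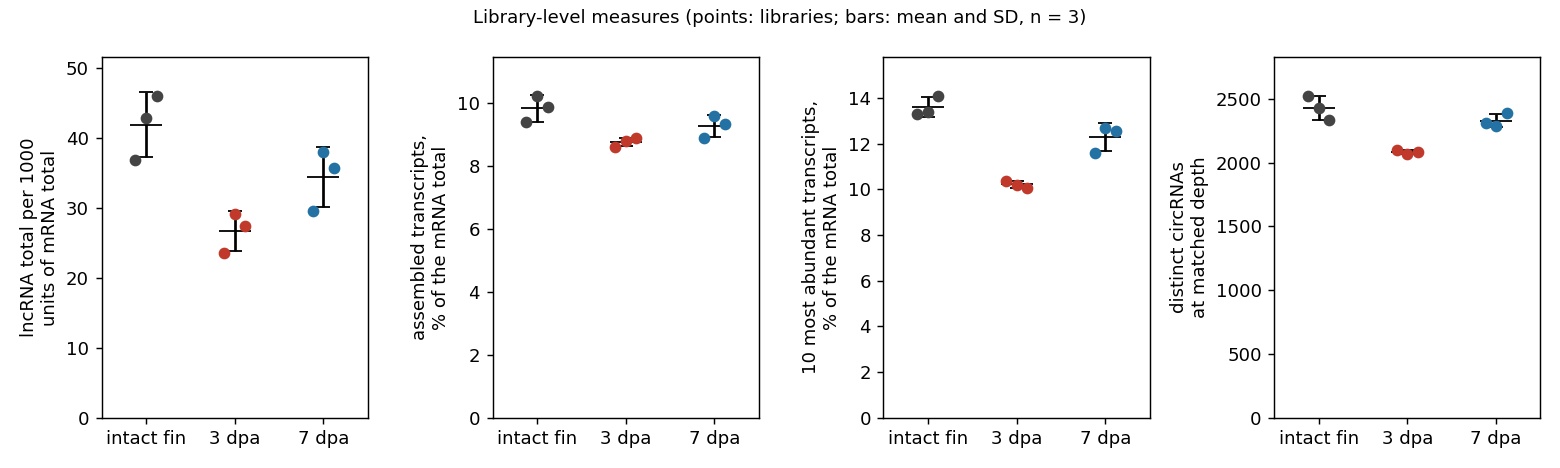
Per-library measures by group, each point 1 library, with the mean and SD of 3 libraries as bars. The lncRNA total per 1000 units of mRNA total falls from a mean of 41.9 to 26.7 at 3 dpa, the assembled share from 9.83% to 8.76%, the share of the 10 most abundant transcripts from 13.6% to 10.22%, and distinct circRNAs at matched depth from 2429 to 2082.

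The comparison of 7 dpa regenerates with intact fins asked which differences were present later. It called 3093 higher and 3289 lower mRNA transcripts (TMM factors gave 3548 and 2723), 25.5% of those tested, and the majority turned in 10 of 20 settings. Changes of at least 2-fold numbered 682 and 581. Among the 50 most abundant transcripts 8 rose and 15 fell. For lncRNAs 32 were higher and 55 lower, with a median log2 change of -0.23, and TMM factors gave 37 and 18 and quantile normalization 42 and 20. The lncRNA count fell to 24 without replicate 2 of 7 dpa, 34 without its replicate 1, 51 without its replicate 3, and 48, 36 and 43 without replicates 1, 2 and 3 of intact fin. For circRNAs 15 were higher and 3 lower. Calls numbered 11 with DESeq2 over 286 circRNAs and 10 with a stricter filter over 606. They numbered 15 with edgeR, 6 without the robust setting and 8 without replicate 2 of 7 dpa.

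The direct comparison of 7 dpa with 3 dpa asked which transcripts moved between the times. It called 2812 higher and 2611 lower mRNA transcripts (TMM factors gave 2573 and 2911). Without replicate 3 of 3 dpa the count was 3262. For lncRNAs 34 were higher and 4 lower, and TMM factors gave 18 and 10 and quantile normalization 16 and 13. Leaving out single libraries gave 18 and 22 lncRNAs without replicates 1 and 3 of 3 dpa, and 23, 25 and 19 without replicates 1, 2 and 3 of 7 dpa. For circRNAs 7 were higher and 5 lower, a balance that turned in 11 of 22 settings. Quantile normalization gave 9 and 2, edgeR 7 and 9, DESeq2 2 and 9, no filter 4 and 9, only the 2 groups compared 3 and 11, and a pseudocount of 1 read 10 and 11. The circRNA count was 0 without the robust setting, 16 with edgeR and 11 with DESeq2 over 286 circRNAs. It was 23 and 27 without replicates 2 and 3 of 3 dpa and 6 without replicate 2 of 7 dpa. In limma 243 circRNAs had an unadjusted p under 0.05, a number that includes chance. All libraries of one group lay above those of the other for 9.31% of circRNAs, against 10% expected by chance without ties.

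**Figure D3:**
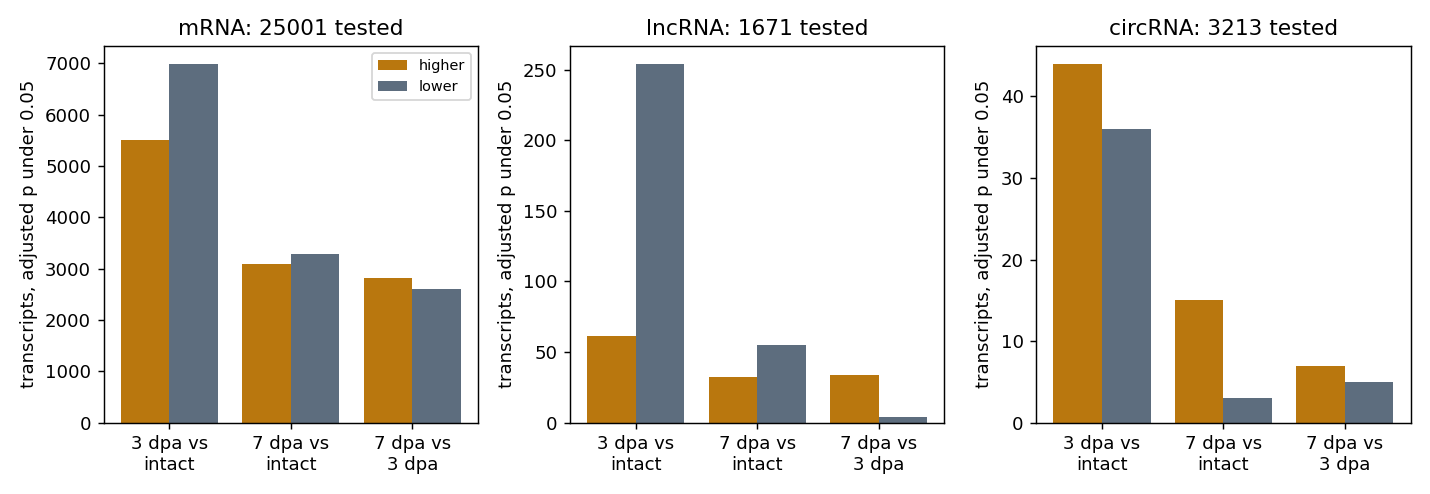
Bars give the number of transcripts higher or lower at a limma adjusted p under 0.05 in each table and comparison, from 0. The mRNA panel holds 5510 higher and 6989 lower transcripts at 3 dpa, the lncRNA panel 61 and 254 and the circRNA panel 44 and 36; mRNA and lncRNA balances move with scaling.

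Of 5510 mRNA transcripts higher at 3 dpa, 2770 (50.3%) were also called higher at 7 dpa, and of 6989 lower ones 3057 (43.7%) were also called lower. Independent lists would share 682 and 919, and simulated unchanged groups against the same intact fins shared 0, a count that the adjusted threshold fixes near 0 and that is no benchmark. At an unadjusted p under 0.05 in limma, 3768 higher and 4517 lower transcripts were shared, against means of 142 and 147 in 20 simulations of unchanged groups. Those simulations held no change at either time. The gap therefore shows that changes were present, not that both times changed the same transcripts. From 3 to 7 dpa 2431 of the higher transcripts moved back and 20 moved further, and of the lower ones 2513 moved back and 8 moved further. Choosing transcripts by their 3 dpa values favours a move back. In 20 simulations in which the 3 dpa change persisted in full, chosen after the data were seen, a mean of 0 higher and 0.05 lower transcripts moved back past the threshold. With no true difference the adjusted threshold is also harder to pass. Noise was drawn apart for each transcript, so variation shared by the transcripts of a library was not simulated. In those simulations 55.0% of higher and 55.5% of lower transcripts had a 7 dpa estimate between intact fin and 3 dpa, against 88.1% and 90.3% in the data. Across transcripts, which are not independent, the log2 changes at both times correlated at r = 0.836, against 0.499 in simulated unchanged groups, with a covariance of 0.361 against 0.0281. The covariance from the shared intact fins is held in the simulated value. The excess of shared calls over independent lists may come in part from those shared libraries.

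**Figure D4:**
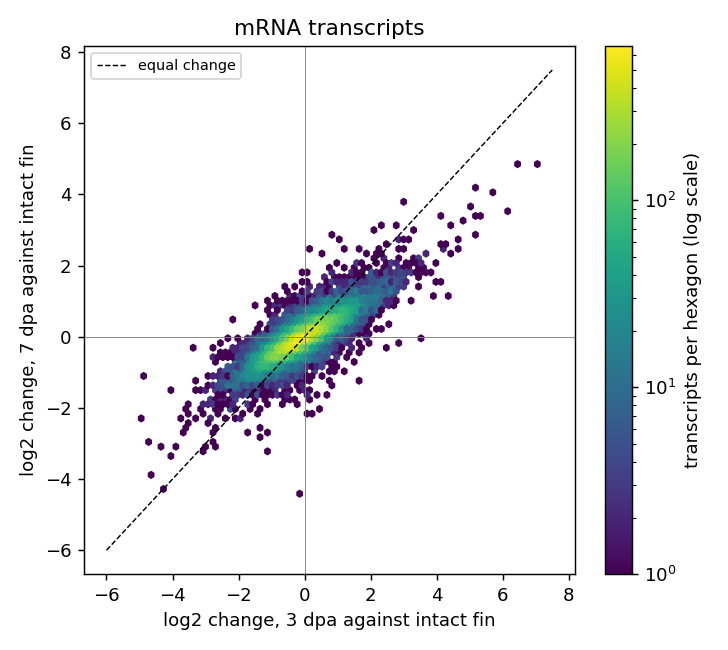
Log2 change at 3 dpa (horizontal) and 7 dpa (vertical), both against intact fin, for mRNA transcripts, with the number per hexagon on a log colour scale and a dashed line of equal change. Of transcripts called at 3 dpa, 88.1% of the higher and 90.3% of the lower ones had a 7 dpa estimate between those of intact fin and 3 dpa, against 55.0% and 55.5% in simulations with a fully persisting change; r across transcripts was 0.836, against 0.499 in simulated unchanged groups.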

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

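All tests of the 3 weighed patterns and the bounds that decide them were chosen or written after the results were seen, while the tests between 7 and 3 dpa were planned. Changes of 6 named transcripts against intact fin differed between the times in the direct limma test. The change at 7 dpa minus that at 3 dpa was -2.23 for ENSDART00000132089 (limma adjusted p = 0.00215) and -1.53 for TCONS_00033479 (limma adjusted p = 0.000816). It was 3.77 for TCONS_00034811 (limma adjusted p = 0.000201) and 2.68 for TCONS_00050791 (limma adjusted p = 0.0262), which was listed at 0 at 3 dpa. For lncRNAs it was -2.06 for TCONS_00014589 (limma adjusted p = 0.0172) and 3.08 for ENSDART00000177369 (limma adjusted p = 0.0266). These transcripts were named for their change at 3 dpa, so selection also favours a move back. Among all mRNA transcripts called at 3 dpa, 88.1% of higher and 90.3% of lower ones had a 7 dpa estimate between. In simulations with a fully persisting change and the same selection, at most 55.9% and 56.3% did. With noise drawn apart for each transcript, this argues against selection alone for the mRNA calls as a set. Variation that moves many transcripts of a library together was not simulated, and the observed 3 dpa means were taken as true. The lncRNAs were not covered by those simulations. The calls of TCONS_00050791, TCONS_00014589 and ENSDART00000177369 between the times were lost in several settings.

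The first pattern is the lower lncRNA values at 3 dpa. With values as deposited, the lncRNA median lay -0.288 from the median of mRNA lists matched on level, outside their range. That range reflects which transcripts were drawn, not the spread between libraries. The gap argues against low expression alone only if both tables were scaled together, which is unknown. A scaling of libraries shared with the mRNA table is argued against too, since the median was still -0.388 with factors of that table. A scaling of the lncRNA table apart from the mRNA table cannot be told apart from a real fall, because factors of the lncRNA table itself centre it, which left a median of -0.0521. A difference of the regenerate stays open and untested.

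The second pattern is the excess of falls among assembled mRNA transcripts at 3 dpa. Low expression alone is argued against in these libraries, since their median lay -0.130 from that of annotated lists matched on level. Their median was -0.216, and the lists ranged from -0.107 to -0.0637. That range reflects which transcripts were drawn, not the spread between libraries. The assembled share of the mRNA total lost its call without some single libraries. Reads split between assembled and annotated models of one gene stay open, since the IDs are not paired with genes here, and so does a biological difference at 3 dpa.

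The third pattern is the lower number of distinct circRNAs at 3 dpa. The number of circRNA reads is argued against, since at equal reads the ratio to intact fin was 0.857 and every 3 dpa library lay below every intact fin library. A few circRNAs taking most reads are argued against as well, since the ratio without the 10 most abundant was 0.850. The circRNA caller and a change in RNA composition stay open, and the data may reflect either.

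For each comparison of 2 groups, only 1 of the 10 splits of the 6 libraries gave as many calls, the real one, and 10 splits are too few for a share under 0.05. The real and highest other counts for mRNA were 12499 and 1 at 3 dpa, 6382 and 12 at 7 dpa, and 5423 and 2 between the times. For lncRNAs they were 315 and 0, 87 and 1, and 38 and 1, and for circRNAs 80 and 4, 18 and 4, and 12 and 4. For the test over all 3 groups, only 1 of 100 splits of the 9 libraries, the real one, gave as many. A random labelling of the libraries is thus argued against. Chance differences between fish are not excluded, since the number of fish per library is unknown. The counts were 11546 against a highest other of 5204 for mRNA, 259 against 98 for lncRNAs and 78 against 46 for circRNAs.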

How the results depend on the processing

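The per-library measures, their alternatives, the equal mRNA plus lncRNA total, the factors of the mRNA table, and the pseudocount of 1 read, edgeR and DESeq2 for circRNAs were chosen after seeing the data. The log2 changes of the 12 named transcripts and the 3 per-library ratios kept their sign in every setting, but balances of higher against lower calls did not. For mRNA the majority turned in 2 of 20 settings at 3 dpa, 10 of 20 at 7 dpa and 7 of 20 between the times. For lncRNAs it turned in 1, 2 and 0 of 21, and for circRNAs in 4, 0 and 11 of 22, with ties in another 2, 0 and 2. Requiring a fold of at least 2 left 4342, 1263 and 837 mRNAs (3 dpa, 7 dpa and between the times) and 1104 shared calls, and a stricter filter left 8169 mRNAs at 3 dpa, by construction. With only the 2 groups compared, calls were 48 for lncRNAs at 7 dpa and 25 for circRNAs at 3 dpa, where fewer samples set the spread. No pairing of the samples by replicate number was seen (correlations of same-numbered libraries -0.0454 to 0.0706). Such correlations with 3 libraries per group cannot exclude pairing. A replicate block gave 47 lncRNAs at 7 dpa, 19 lncRNAs and 20 circRNAs between the times, and otherwise stayed within 1.5 times. TMM factors gave 55 lncRNAs at 7 dpa. For circRNAs at 3 dpa, 7 dpa and between the times, calls without the robust setting were 35, 6 and 0. A stricter filter gave 10 at 7 dpa and 6 between the times, but only 606 circRNAs were tested, against 3213. DESeq2 gave 43 at 3 dpa and 11 at 7 dpa, over 971 and 286 circRNAs with an adjusted p. A pseudocount of 1 read gave 123 at 3 dpa and 21 between the times. Other causes of these moves were not tested. Leaving out each library gave 3262 to 5341 mRNAs between the times (lowest without replicate 3 of 3 dpa), 24 to 69 lncRNAs at 7 dpa and 18 to 39 between the times, and 8 to 22 circRNAs at 7 dpa and 6 to 27 between the times. The assembled share of 3 dpa over intact fin ranged from 0.871 to 0.909. The test of that share over the 3 groups lost its call without any of 6 libraries. For the 12 named transcripts and 3 comparisons each, 645 of 717 alternative values kept their side of the threshold, 68 lost the call and 4 gained it. Alternatives fixed beforehand on gene lists, sums per gene symbol, circRNAs and host genes, circRNA scaling by the mRNA total and count models for mRNA and lncRNA were not run, since the IDs or units did not allow them. Unknown depth limits the low mRNA and lncRNA values, and a median of 1.22 reads per tested circRNA and library limits circRNA calls.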

Other observations

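These counts were all chosen after the data were seen. A small set of mRNA transcripts differed at 7 dpa from both other groups without a call at 3 dpa, 107 of them higher and 49 lower. Another 17 transcripts were lower at 3 dpa and higher at 7 dpa than in intact fin, and 4 were higher and then lower.

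The share of falls among mRNA calls at 3 dpa depended on level under some scalings only, and the difference between levels was not tested. With values as deposited it was 65.1% in the lowest of 4 equal bins of transcripts by mean signal, 62.7% and 55.8% in the middle bins and 47.4% in the highest. With TMM factors the lowest and highest bins had 60.3% and 40.7%, but with quantile normalization 52.3% and 51.1%, so no trend with level is claimed.

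Of 25001 mRNA transcripts, 39 were listed at 0 in 1 library and at a signal of at least 10 in another library of the same group, and 5 of these were called at 3 dpa. Among 343 circRNAs with at least 50 reads over all libraries, 3 pairs with nearby numbers had nearly equal reads in every library (within 5% in sum), for example novel_circ_004292 with 1547 and novel_circ_004294 with 1551.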
